A study of Mus musculus with 9 samples.

How the data were processed

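Gene expression was measured by paired-end RNA sequencing of poly(A) RNA from mouse colon, in 9 libraries from 9 mice. The labels name the ABclonal mRNA-seq kit with oligo(dT) beads and do not state strandedness. Per the submitters' processing notes the tools were HISAT2, featureCounts and DESeq2, with the builds GRCm38 and mm10. Versions, annotation release and read filters are not given in the sources used here. The deposited table lists 33539 genes, 1042 of them at 0 in every library. Per the file headers it holds a raw count for each gene and library, and these are whole numbers with totals from 34.4 to 44.3 M counts. Per the file headers it also holds an FPKM value for each gene and library, made by the authors. For all 32497 genes with an FPKM above 0 it equals the count divided by the library total and by a whole length per gene, to within 0.01 bases. FPKM values were used for this check alone.

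Genes carry the symbols and Ensembl identifiers of the deposited table. Of these identifiers 32869 are in GENCODE release M21 on GRCm38, which gave coordinates, and 670 are not. The length behind the FPKM equals the exon union of that release for 98.2% of 31905 genes compared. How reads that map to several genes or to overlapping genes were counted is not stated, which bears on families of similar genes such as Ly6g, Ugt2b5, Cyp2c66, Cyp2d26, Btnl1, H2-T3, Apol9b and the Oas and Slfn genes.

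The labels disagree on 3 points. The age is 8 weeks in the design text and 6 weeks in the treatment protocol, irradiation is abdominal in the former and of the whole body in the latter, and Con mice received saline in the former and PBS in the sample labels. The doses of CF-2 came 1 h before irradiation and 24, 48 and 72 h after it. Library numbers run from 2 to 4 in Con and IR and from 1 to 3 in IR+CF-2, nothing states that equal numbers belong together, and no batch is given. A check of sex-linked genes found 0 libraries that did not match their labels.

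Counts were fitted with edgeR 4.0.16 in R 4.3.3: filterByExpr on the 3 groups, TMM scaling, and the quasi-likelihood F-test with robust = TRUE. A single fit covered all 9 libraries with group as the only term, and gave 3 comparisons (IR with Con, IR+CF-2 with IR, IR+CF-2 with Con). 19174 genes were tested and 14365 were left out by the filter. Tests were 2-sided, with Benjamini-Hochberg adjusted p under 0.05 over the genes of a comparison. The standard error is the absolute log2 fold change divided by the square root of F. The biological coefficient of variation was 30.6%. In a library 3 counts, taken as the floor, are 0.0677 to 0.0871 CPM. Floors cover counting error only, since PCR copies are not told apart without molecular identifiers. Principal components were computed from log2 CPM of the tested genes.

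Before the data were examined, 40 gene lists (pathways and markers of cell types and gut regions) and the rule for named genes were fixed. Lists with at least 5 tested members, 39 in all, were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, with p adjusted over the lists of a comparison. Each test was repeated with an estimated correlation and with fry, which asks whether the genes of a list move on balance in a single direction. Genes were named if they stand in the title of the series, if they had the 10 largest increases or decreases among genes past the test with separate groups and a mean of at least 5 CPM in the higher group, or if they had the 4 smallest adjusted p in a described list. Predicted genes, clone names, pseudogenes and receptor segments were left out of that rule, and not every gene that meets it is printed. Described are the 30 lists called by camera in any comparison or fixed as central, and the other 10 have a sentence among the closing observations.

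The pipeline was tested on simulated data with the means, depths and dispersions of these libraries and 200 changed genes. It recovered 16, 22 and 18% of the 2-fold changes and 73, 75 and 77% of the 4-fold changes in the 3 comparisons. False calls were 8.25, 9.35 and 1.04% of the calls, above 5% in the comparisons of IR with Con and of IR+CF-2 with IR. For lists, 10 of 10 changed by 1.5-fold were called and 0 of 30 unchanged, but genes were simulated without correlation between them. A further 20 simulations without any change gave the covariance and the shared calls to expect from comparisons that use the same libraries if neither irradiation nor CF-2 acts.

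Alternatives fixed before the data were examined were RLE and upper quartile scaling, no filter and a stricter filter, DESeq2 1.42.0, limma-voom, a fit on the compared groups alone, the library number as a replicate block, an adjusted p under 0.01, a limit of 2-fold, and leaving out abundant and mitochondrial genes or each library in turn. Alternatives added after seeing the data were a position term (log2 CPM of Hoxa13), a fit with robust = FALSE, and a fit without Con 3, IR 4 and IR+CF-2 2. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Raw reads, splicing and the significance calls of the submitters were not used here.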

Results

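RNA was sequenced from the colon of 9 wild-type male C57BL/6 mice, 3 in each of 3 groups, taken 84 h after irradiation. Con mice were not irradiated, IR mice received 13 Gy, and IR+CF-2 mice received 13 Gy and 4 intraperitoneal doses of the compound CF-2 at 7.5 mg/kg. CF-2 is a code name, and the labels give no structure for it. The title of the series names agonism at the cannabinoid receptor CB2 (gene Cnr2), β-catenin (Ctnnb1) and HoxA10 (Hoxa10) in radiation injury of the intestinal epithelium. No group received CF-2 without irradiation. Libraries keep the numbers of their labels (Con 2, 3 and 4, IR 2, 3 and 4, IR+CF-2 1, 2 and 3). Their totals were 40.6, 42.4 and 37.7 M counts in Con, 34.4, 36.4 and 38.9 M in IR, and 40.5, 39.7 and 44.3 M in IR+CF-2. Levels are given as CPM, mean ± SD with n = 3 mice per group, and log2 fold changes as estimate ± standard error from edgeR with 3 mice per group.

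The first principal component held 38.6% of the variance and placed the Con libraries between 59 and 67.3, IR 2 and IR 3 at -23 and -28.7, and the IR+CF-2 libraries between -83 and -22.6. IR 4 lay nearer to Con, at 23. The second component, with 24.4%, set IR+CF-2 2 apart at 95.2, where the next library, Con 2, lay at 30.5. Mitochondrial transcripts took 5.29 ± 0.259% of the counts in Con, 4.67 ± 0.528% in IR and 3.16 ± 0.619% in IR+CF-2 (SD, n = 3). By a 2-sided exact permutation test the share gave p = 0.2 for IR against Con, 0.1 for IR+CF-2 against IR and 0.1 for IR+CF-2 against Con, where 0.1 is the smallest p that 3 mice against 3 allow.

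**Figure D1:**
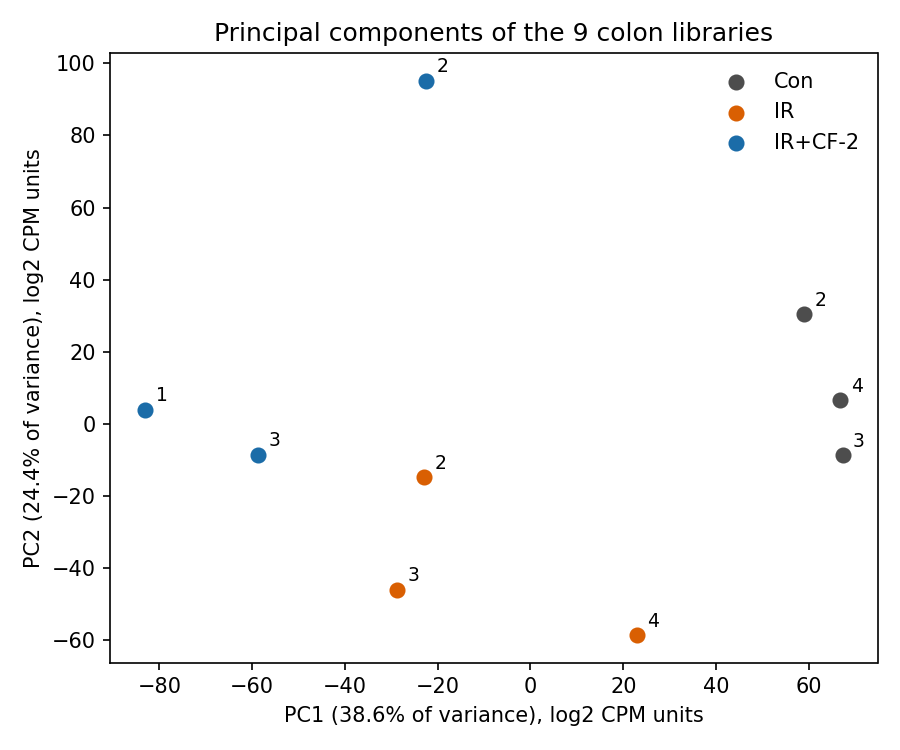
Principal components of the 9 libraries (log2 CPM of the tested genes), each point a library coloured by group, with the share of variance on each axis. IR 4 sits at 23 on the first component, between Con and the other IR libraries, and IR+CF-2 2 at 95.2 on the second.

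The comparison of IR with Con asks how the colon had responded 84 h after 13 Gy. Targets of the tumour suppressor p53 rose: 15 of the 26 measured passed the test, all higher in IR, among them the receptor gene Eda2r (log2 fold change 3.90 ± 0.45, adjusted p = 0.0222, 1.47 ± 0.313 CPM in Con and 21.9 ± 11.2 in IR, n = 3 each). The stress cytokine Gdf15 rose by 3.53 ± 0.38, the pro-apoptotic Bax by 1.48 ± 0.20 and the cyclin Ccng1 by 1.85 ± 0.27. Interferon-stimulated genes went the other way, with 13 of 24 lower in IR, and the antiviral enzyme Oas2 went from 292 ± 7.78 to 20.4 ± 4.8 CPM (-3.84 ± 0.38, adjusted p = 0.0206). Markers of B and plasma cells (9 of 15) and of T and NK cells (8 of 19) also fell.

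Adjusted over the list alone, 20 p53 targets were higher and 1 lower, with a list median of 1.08 (camera adjusted p = 5.21e-20, adjusted p = 0.12 with an estimated correlation). Of 28 proliferation genes 6 were higher, and 27 adjusted over the list alone, with a median of 1.19 (camera adjusted p = 5.21e-20, adjusted p = 0.266 with an estimated correlation). The replication helicase genes Mcm3 (1.54 ± 0.31) and Mcm5 (1.40 ± 0.28) and the ribonucleotide reductase gene Rrm1 (1.40 ± 0.25) were among them. DNA repair genes were higher for 9 of 25, and 19 adjusted over the list alone (camera adjusted p = 1.44e-09, adjusted p = 0.266 with an estimated correlation), including the exonuclease Exo1 (1.503 ± 0.26), the helicase Blm (1.46 ± 0.31) and Brca2 (0.95 ± 0.20). In the list of crypt stem and progenitor cells 4 of 19 rose, namely Sox9 (0.77 ± 0.16), Cd44 (1.42 ± 0.30), Cdca7 (0.69 ± 0.15) and Ephb3 (0.92 ± 0.20), and 9 adjusted over the list alone (camera adjusted p = 8.02e-05, adjusted p = 0.12 with an estimated correlation). Among β-catenin targets 6 of 21 rose, with Ccnd1 at 1.84 ± 0.36 and Myc at 1.37 ± 0.27 (camera adjusted p = 0.000164, adjusted p = 0.397 with an estimated correlation). This list shares genes with the stem and progenitor list, Sox9, Cd44 and Ephb3 among them, so these results are not independent. Regenerative and fetal-like epithelial markers had a median of 1.03 (camera adjusted p = 0.000147, adjusted p = 0.336 with an estimated correlation), with 2 of 20 past the test, among them Il1rn, and 9 adjusted over the list alone. Of the oxidative stress genes 2 of 21 rose (camera adjusted p = 0.00387, adjusted p = 0.317 with an estimated correlation), the glutathione peroxidase Gpx2 (2.14 ± 0.39) and the haem oxygenase Hmox1 (1.34 ± 0.30). Outside the lists, Atg9b (6.78 ± 1.01), Syt8 (4.56 ± 0.63), the transcription factor Grhl3 (4.33 ± 0.57) and the metalloproteinase Mmp7 (5.51 ± 1.24) were among the largest increases, and the tight junction gene Cldn4 rose by 2.47 ± 0.42, the 1 called member of 21 junction genes (camera adjusted p = 0.243, adjusted p = 0.75 with an estimated correlation).

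The interferon list had a median of -2.12 (camera adjusted p = 6.41e-19, adjusted p = 0.266 with an estimated correlation), and its mean level stood 0.81 (log2) above the Con mean in Con 3 and at -0.42 and -0.38 in Con 2 and Con 4. Slfn4 (-3.56 ± 0.41), Ifi44 (-3.54 ± 0.57), Isg15 (-3.29 ± 0.65), Phf11a (-3.52 ± 0.75) and Apol9b (-3.51 ± 0.64) were among the largest decreases, and the regulator Irf7 fell by 1.98 on the log2 scale. B and plasma cell markers had a median of -2.38 and all 15 were lower adjusted over the list alone (camera adjusted p = 1.90e-18, adjusted p = 0.0179 with an estimated correlation). They include the B cell receptor gene Cd79b (-3.09 ± 0.40) and the antibody chain Igha (-1.38 ± 0.22). All 19 T and NK markers were lower adjusted over the list alone, with a median of -1.95 (camera adjusted p = 5.22e-18, adjusted p = 0.12 with an estimated correlation), for example Cd3g (-2.43 ± 0.35) and Cd8a (-2.06 ± 0.39). The antigen presentation gene H2-Ob fell by 4.00 on the log2 scale, the 1 called gene of 11 in the MHC class II list (camera adjusted p = 0.0942, adjusted p = 0.734 with an estimated correlation). The neutrophil list had a median of 2.29 with 1 of 11 past the test (camera adjusted p = 0.0024, adjusted p = 0.503 with an estimated correlation), and that gene, Ly6g, rose by 5.67 ± 0.73 to 52.4 ± 33.2 CPM while S100a8 stood at 0.588 ± 0.659 CPM. How reads shared by Ly6g and similar genes were counted is not stated. The neutrophil mean against Con was 1.5, 2.34 and 0.53 in IR 2, 3 and 4. Over 17 alternatives the list median ran from 0.06 to 3.58 (camera adjusted p from 1.31e-05 to 0.434). Tuft cell markers had a median of -0.92, with 0 of 9 past the test over all genes and 6 adjusted over the list alone (camera adjusted p = 0.000352, adjusted p = 0.266 with an estimated correlation).

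Further lists were called without a gene past the test. Smooth muscle had a median of -0.89 (camera adjusted p = 3.08e-05, adjusted p = 0.503 with an estimated correlation), enteric neurons and glia -1.05 (camera adjusted p = 0.000147, adjusted p = 0.503 with an estimated correlation), the Hox genes -0.36 (camera adjusted p = 0.00314, adjusted p = 0.503 with an estimated correlation) and the endocannabinoid system -0.55 (camera adjusted p = 0.0176, adjusted p = 0.226 with an estimated correlation). Smooth muscle markers stood at -1.43 in IR 4 and -0.79 in Con 3 against the Con mean, lower than in their group neighbours. Of the genes in the title, Cnr2 (chromosome 4, on GRCm38) had 1.3 ± 0.563 CPM in Con and 0.858 ± 0.134 in IR (-0.59 ± 0.38, adjusted p = 0.362). Ctnnb1 (chromosome 9) had 716 ± 105 and 859 ± 59.5 CPM (0.26 ± 0.14, adjusted p = 0.281) and Hoxa10 (chromosome 6) 36.6 ± 27.8 and 5.77 ± 3.02 CPM (-2.66 ± 0.75, adjusted p = 0.0774). Hoxa10 stayed short of the threshold in 16 of 18 alternatives (edgeR or DESeq2 adjusted p from 0.00117, with DESeq2, to 0.399). Ctnnb1 did so in 17 of 18 (from 0.029 to 0.691). Called lists apart from these did not include inflammatory cytokines (median 0.54, camera adjusted p = 0.0733) or macrophages (median 0.18, camera adjusted p = 0.548). The cytokine list gained the call in 7 of 17 alternatives, and its mean against Con was 0.84, 1.15 and -0.05 in IR 2, 3 and 4. Fibroblast markers had a median of -0.04 and a mean of 0.09, opposite in sign (camera adjusted p = 0.851).

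Of 19174 genes tested, 454 were higher and 162 lower in IR at an adjusted p under 0.05, and 4591 had an unadjusted p under 0.05. The split was 173 higher and 104 lower with RLE scaling and 166 and 136 with upper quartile scaling. Leaving out any 1 library changed the counts widely, and each such fit also has fewer mice in a group. Without IR 4, 789 were higher and 402 lower. Without Con 2, Con 4, IR 2 or IR 3 none was higher and 1, 2, 1 and 1 were lower. Without Con 3 the counts were 4 and 10. DESeq2 called 1330 higher and 800 lower, limma-voom 111 and 65, and of the 16 lists called by camera the B and plasma cell list alone held with an estimated correlation. The position term (log2 CPM of Hoxa13) left 15 genes higher and 31 lower.

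**Figure D2:**
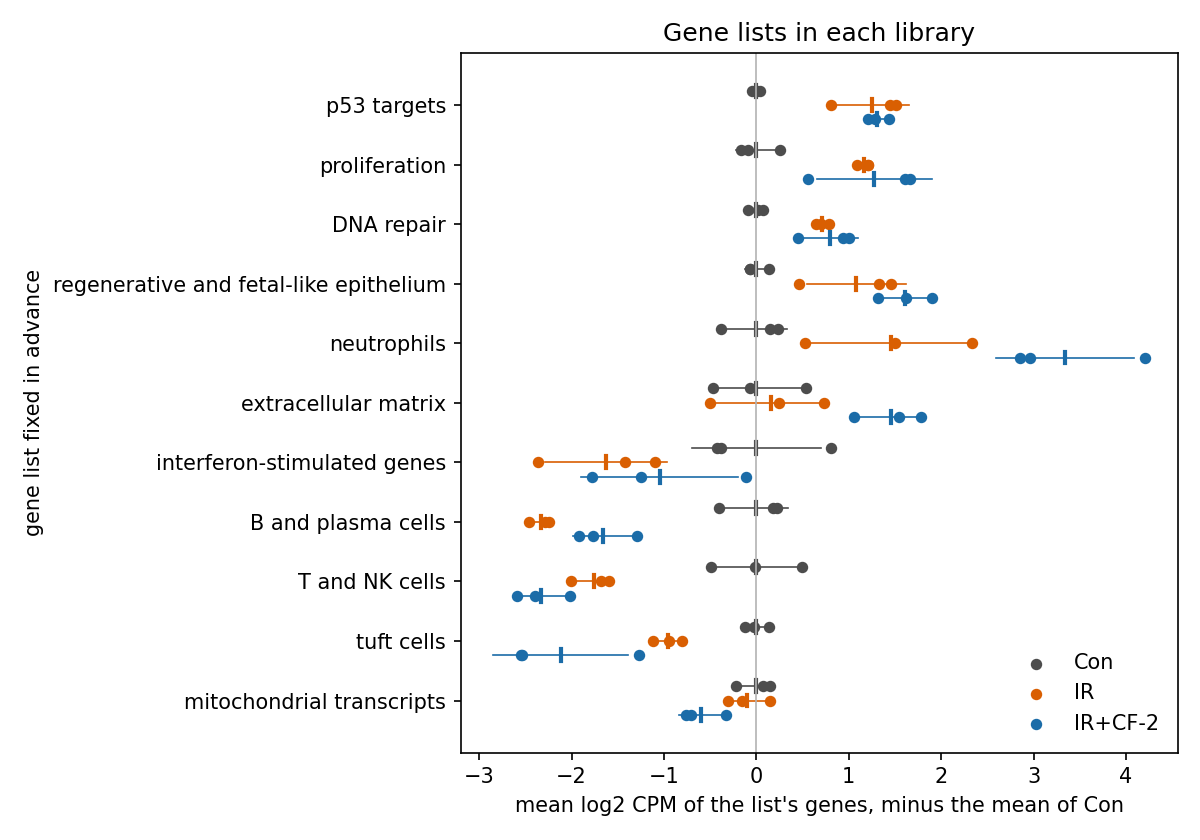
Mean log2 CPM of the genes of each list, minus the mean of Con, for each library (points), with group means (vertical bars) and SD (horizontal lines, n = 3). T and NK markers lie at -2.0 in IR 2, -1.69 in IR 3, -1.60 in IR 4 and between -2.59 and -2.01 in IR+CF-2, and neutrophil markers between 2.86 and 4.20 in IR+CF-2.

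The comparison of IR+CF-2 with IR asks what differed in irradiated colon with CF-2. The effect of CF-2 and the stretch of colon sampled cannot be told apart in it. 11 genes rose and 47 fell. The potassium pump Atp12a, a member of the distal colon list, rose from 2.79 ± 1.43 to 488 ± 560.3 CPM (n = 3 each, log2 fold change 7.45 ± 0.96, adjusted p = 0.0301). It had 188, 1135 and 142 CPM in the 3 treated mice. The colonic hormone gene Insl5 (5.50 ± 0.87), the neutrophil chemokine Cxcl1 (3.57 ± 0.54), the siderophore-binding Lcn2 (2.12 ± 0.32) and the hypoxia regulator Hif1a (1.70 ± 0.23) rose too. The disaccharidase Sis, a member of the small intestine list, fell from 8.06 ± 2.14 to 0.0876 ± 0.113 CPM (-6.43 ± 0.73, adjusted p = 0.0172). The glutamate receptor subunit Grin3a (-5.11 ± 0.27, adjusted p = 0.000311), the butyrophilin-like Btnl1 (-3.999 ± 0.34) and the cell cycle inhibitor Cdkn1c (-2.44 ± 0.19) fell too.

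The other increases among the genes named by rule were Ccn2 (1.36 ± 0.17), Rgcc (1.17 ± 0.18), the plasminogen activator Plat (1.13 ± 0.17), Tln2 (1.11 ± 0.17) and Smim31 (1.07 ± 0.15). The other decreases were Malrd1 (-4.32 ± 0.69), Cyp2d26 (-3.72 ± 0.46), the phosphate transporter family member Slc17a4 (-3.66 ± 0.36), the neurotrophin receptor Ntrk2 (-2.90 ± 0.43), Myo3a (-2.40 ± 0.32) and the protease Prss23 (-2.31 ± 0.26). In these genes all 3 libraries of a group lay above the 3 of the other.

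Gene by gene, the lists held few calls. Prom1 (-1.59 ± 0.23, adjusted p = 0.0396) fell among 19 stem and progenitor genes (camera adjusted p = 0.21, adjusted p = 0.483 with an estimated correlation). No p53 target, proliferation gene, DNA repair gene or β-catenin target passed the test, and their medians were 0.04, 0.16, 0.12 and 0.10 (camera adjusted p = 0.822, 0.199, 0.223 and 0.396). The mean proliferation level against Con was 1.66, 0.56 and 1.61 in IR+CF-2 1, 2 and 3 and 1.09 to 1.21 in IR. Without IR+CF-2 2 the medians of proliferation and DNA repair genes were 0.46 and 0.27 (camera adjusted p over 17 alternatives from 3.39e-10 to 0.754 and from 0.000971 to 0.977). In the inflammatory cytokine list 1 of 22 passed the test, Cxcl1, and 4 were higher adjusted over the list alone (camera adjusted p = 5.23e-06, adjusted p = 0.288 with an estimated correlation). Regenerative markers had a median of 0.62 (camera adjusted p = 2.60e-05, adjusted p = 0.288 with an estimated correlation), with Ccn2 past the test. Neutrophil markers had a median of 1.69 (camera adjusted p = 2.20e-07, adjusted p = 0.288 with an estimated correlation), macrophage markers 0.74 (camera adjusted p = 1.92e-08, adjusted p = 0.288 with an estimated correlation) and B and plasma cell markers 1.04 (camera adjusted p = 1.60e-05, adjusted p = 0.256 with an estimated correlation), with no gene past the test. Adjusted over the list alone 6 of 11, 3 of 16 and 8 of 15 were higher. T and NK markers had a median of -0.50 (camera adjusted p = 0.00596, adjusted p = 0.457 with an estimated correlation) and interferon-stimulated genes 0.72 (camera adjusted p = 0.000376, adjusted p = 0.565 with an estimated correlation), and MHC class II genes 0.86 (camera adjusted p = 0.0199, adjusted p = 0.457 with an estimated correlation). The MHC class II mean against Con was 0.71 in IR+CF-2 1 and -0.52 and -0.50 in IR+CF-2 2 and 3. Without IR+CF-2 1 the medians of the MHC class II and interferon lists were 0.20 and 0.27. Their camera adjusted p over 17 alternatives ran from 0.00117 to 0.771 and from 4.60e-18 to 0.502.

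Stromal lists were called higher. Extracellular matrix genes had a median of 1.16, with 18 of 23 higher adjusted over the list alone and none over all genes (camera adjusted p = 6.04e-17, adjusted p = 0.288 with an estimated correlation). Fibroblast markers had a median of 1.14 (camera adjusted p = 4.66e-08, adjusted p = 0.288 with an estimated correlation), smooth muscle 0.73 (camera adjusted p = 2.69e-05, adjusted p = 0.456 with an estimated correlation), endothelial cells 0.69 (camera adjusted p = 0.000858, adjusted p = 0.483 with an estimated correlation), enteric neurons and glia 0.47 (camera adjusted p = 0.0172, adjusted p = 0.58 with an estimated correlation) and Wnt ligands and regulators 0.92 (camera adjusted p = 0.000173, adjusted p = 0.288 with an estimated correlation). Among these lists the mean level of the fibroblast list, against Con, was 1.65 in IR+CF-2 2 and -0.79 in IR 4. With a position term (the level of Hoxa13 in each library) the medians of the matrix, fibroblast, muscle, endothelial and enteric lists were below 0. Muscle (-0.73) was among those past the threshold, since its camera adjusted p stayed at 0.0177 or below over 17 alternatives. The T and NK median was then 0.46 (camera adjusted p = 0.0238, and from 0.000101 to 0.144 over 17 alternatives). Lists called lower were absorptive colonocytes (-0.59, camera adjusted p = 0.00032, adjusted p = 0.288 with an estimated correlation), tuft cells (-0.50, camera adjusted p = 2.86e-05, adjusted p = 0.288 with an estimated correlation), epithelial junctions (-0.31, camera adjusted p = 2.03e-05, adjusted p = 0.288 with an estimated correlation), small intestine (-0.38, camera adjusted p = 0.00693, adjusted p = 0.288 with an estimated correlation) and mitochondrial transcripts (-0.53, camera adjusted p = 3.78e-06, adjusted p = 0.38 with an estimated correlation). Mitochondrial transcripts are counted in the mitochondrial share, which is thus not a separate result. The share was 4.67 ± 0.528% in IR and 3.16 ± 0.619% in IR+CF-2 (SD, n = 3).

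The genes of the title did not pass the test. Hoxa10 (chromosome 6, 52231197 to 52240854) had 5.77 ± 3.02 CPM in IR and 65.9 ± 21.1 in IR+CF-2 (3.51 ± 0.77, adjusted p = 0.0942). Its level in Con ran from 5.78 CPM in Con 3 to 59.8 in Con 2, a 10.3-fold range. It stayed short of the threshold in 16 of 18 alternatives and passed with DESeq2 and without Con 3, IR 4 and IR+CF-2 2. Ctnnb1 had 859 ± 59.5 CPM in IR and 644 ± 30.1 in IR+CF-2 (-0.42 ± 0.14, adjusted p = 0.224), and Cnr2 0.858 ± 0.134 and 1.09 ± 0.123 CPM (0.34 ± 0.38, adjusted p = 0.728). The endocannabinoid list had a median of -0.08 (camera adjusted p = 0.168).

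Hox genes split by cluster. Of HoxA genes 9 to 13, all 4 measured had higher values in IR+CF-2 than in IR (median 3.77), and of HoxB genes 1 to 8 all 7 had lower values (median -2.16). Hoxb3 passed the test (-2.16 ± 0.32, adjusted p = 0.0403). Over all 30 Hox genes the median was -0.51 and the mean 0.27, opposite in sign (camera adjusted p = 0.0418, adjusted p = 0.483 with an estimated correlation). In 7 of 17 alternatives the call was lost. The distal colon list had a median of 4.37 (camera adjusted p = 6.76e-06, adjusted p = 0.288 with an estimated correlation) and the proximal colon list -2.50 (camera adjusted p = 0.000371, adjusted p = 0.256 with an estimated correlation), where Cyp2c55 was at -3.59 ± 0.58 and Mptx1, the opposite way, at 9.76 ± 2.09. IR+CF-2 2 held Hoxb13 at 282 CPM, where IR+CF-2 1 and 3 had 8.49 and 1.21 and every IR library 0. HoxA genes were also high in Con 2 and Con 4 and low in Con 3: Hoxa9 had 93.2, 72.1 and 3.81 CPM there, and Hoxb3 11.2, 12.7 and 14.1. Hoxa13 had 43.2, 8.07 and 1.05 CPM, so it was less high in Con 4.

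**Figure D3:**
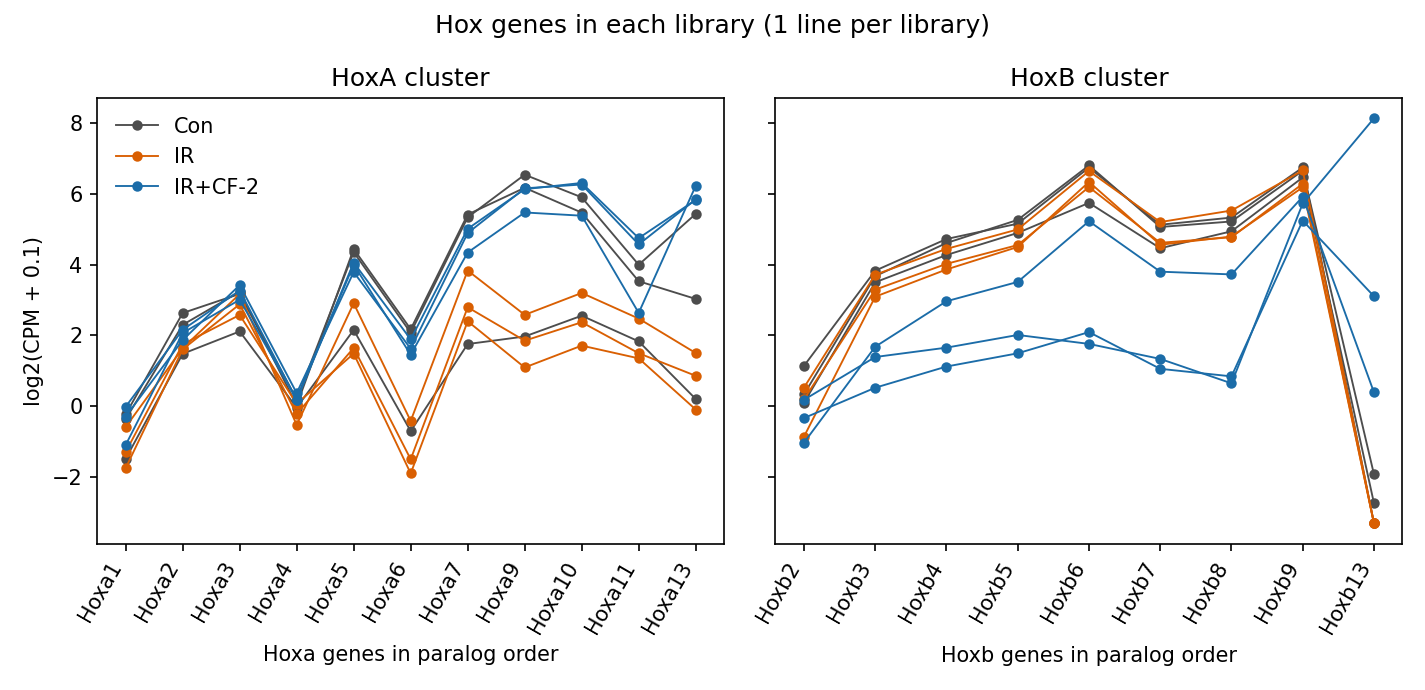
Level of HoxA and HoxB genes (log2 of CPM with 0.1 added) in paralog order, a line for each library coloured by group. Hoxa10 has 59.8 and 44.3 CPM in Con 2 and Con 4, 5.78 in Con 3, 3.17 to 9.08 in IR and 41.7 to 79.3 in IR+CF-2.

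At an unadjusted p under 0.05 there were 2792 genes in IR+CF-2 against IR. Without IR+CF-2 2 the counts were 144 higher and 453 lower, without IR+CF-2 3 they were 17 and 41, and without IR 2, IR 3, IR 4 or IR+CF-2 1 none was higher and 9, 5, 20 and 6 were lower. DESeq2 called 453 higher and 491 lower. The position term, which nearly follows these groups, left 0 genes while the log2 fold changes of the 58 correlated at 0.981 with those above. No list held with an estimated correlation.

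The comparison of IR+CF-2 with Con asks how far the treated, irradiated colon lay from the unirradiated colon. 2152 genes were higher and 1525 lower. Neutrophil markers rose, with 8 of 11 past the test (camera adjusted p = 7.09e-08, adjusted p = 0.255 with an estimated correlation). The calgranulin S100a8 went from 0.0493 ± 0.0484 to 5.63 ± 2.68 CPM, with 6 counts in all of Con (fitted log2 fold change 6.71 ± 1.07, adjusted p = 0.00968, n = 3 each) and Ly6g from 1.02 ± 0.679 to 242 ± 71.5 CPM (7.88 ± 0.79). The Ly6g level may hold reads of similar genes, since the counting of shared reads is not stated. T and NK markers fell, 18 of 19 (camera adjusted p = 5.92e-17, adjusted p = 0.127 with an estimated correlation), with Cd8a at -4.19 ± 0.43 and Cd7 at -3.32 ± 0.45. Tuft cell markers fell for 7 of 9 (camera adjusted p = 6.84e-08, adjusted p = 0.127 with an estimated correlation), with Trpm5 at -3.38 ± 0.54 and Sh2d6 at -3.42 ± 0.43.

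The p53 targets Gdf15 (4.58 ± 0.39), Eda2r (4.01 ± 0.45) and Zmat3 (1.88 ± 0.26) were among 18 of 26 that rose, and 1 fell (camera adjusted p = 1.37e-13, adjusted p = 0.132 with an estimated correlation). Proliferation genes rose for 25 of 28 (camera adjusted p = 5.82e-16, adjusted p = 0.272 with an estimated correlation), including Rrm2 (2.66 ± 0.48), and DNA repair genes for 18 of 25 (camera adjusted p = 1.87e-08, adjusted p = 0.258 with an estimated correlation), including Parp1 (1.05 ± 0.14). Regenerative markers rose for 13 of 20 (camera adjusted p = 5.11e-09, adjusted p = 0.127 with an estimated correlation), among them the growth factor Areg (2.84 ± 0.56), Anxa3 (1.88 ± 0.28) and Ccn1 (2.03 ± 0.22). Stem and progenitor genes rose for 6 and fell for 2 of 19 (camera adjusted p = 0.0181, adjusted p = 0.261 with an estimated correlation), with Ascl2 at 1.26 ± 0.30. β-catenin targets rose for 8 of 21 (camera adjusted p = 0.000259, adjusted p = 0.28 with an estimated correlation), and Wnt ligands and regulators for 3 of 22, with 1 lower (camera adjusted p = 0.0984). The Wnt list gained the call in 5 of 17 alternatives. The stem and progenitor list and the β-catenin list share genes, Ascl2 among them.

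Inflammatory cytokines rose for 9 and fell for 1 of 22 (camera adjusted p = 1.60e-05, adjusted p = 0.28 with an estimated correlation), led by Cxcl2 (fitted 8.46 ± 1.48, from 4 counts in all of Con), Cxcl5 (7.47 ± 1.08) and Cxcl1 (5.32 ± 0.60). Macrophage and monocyte markers rose for 9 of 16 (camera adjusted p = 1.60e-05, adjusted p = 0.397 with an estimated correlation), extracellular matrix genes for 8 of 23 (camera adjusted p = 5.90e-09, adjusted p = 0.282 with an estimated correlation) and fibroblast markers for 5 of 14 (camera adjusted p = 0.00043, adjusted p = 0.409 with an estimated correlation). The protease inhibitor Timp1 (2.51 ± 0.35), the metalloproteinase Mmp3 (4.40 ± 0.67) and the BMP antagonist Grem1 (2.73 ± 0.71) were among these. Oxidative stress genes rose for 8 of 21 (camera adjusted p = 0.00238, adjusted p = 0.263 with an estimated correlation), with the cystine transporter Slc7a11 at 3.53 ± 0.59. Smooth muscle (median -0.22, camera adjusted p = 0.55), endothelial cells (0.28, camera adjusted p = 0.55) and enteric neurons and glia (-0.48, camera adjusted p = 0.152) were not called, and no gene of theirs passed the test.

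Interferon-stimulated genes fell for 10 of 24 (camera adjusted p = 4.52e-07, adjusted p = 0.409 with an estimated correlation), with Irf7 at -2.11 ± 0.28, and B and plasma cell markers for 7 of 15 (camera adjusted p = 4.46e-05, adjusted p = 0.127 with an estimated correlation). The mean interferon level against Con was -0.12 in IR+CF-2 1, -1.78 in IR+CF-2 2 and -1.25 in IR+CF-2 3. In the MHC class II list H2-Ob fell (-3.38 ± 0.53), and the list median was 0.61 where camera gave the direction as down (adjusted p = 0.992). Metabolic genes among the decreases were the detoxification enzymes Ugt2b5 (-6.43 ± 1.19) and Cyp2c66 (-5.81 ± 0.89) and the lipid regulator Ppara (-2.95 ± 0.42). The lipid and ketone list had 3 higher and 5 lower of 20 (camera adjusted p = 0.031, adjusted p = 0.517 with an estimated correlation). In 6 of 17 alternatives this call was lost. Absorptive colonocyte markers had 1 higher and 5 lower of 20 (camera adjusted p = 0.00126, adjusted p = 0.28 with an estimated correlation), with the carbonic anhydrase Car1 at -2.09 ± 0.40. Junction genes had 1 higher and 5 lower of 21 (camera adjusted p = 0.104). Of the endocannabinoid genes 3 of 14 fell (camera adjusted p = 0.0029, adjusted p = 0.127 with an estimated correlation), Ppara, the monoacylglycerol lipase Mgll (-1.63 ± 0.26) and the anandamide hydrolase Faah (-0.55 ± 0.14). Mitochondrial transcripts fell for 7 of 13 (camera adjusted p = 5.54e-05, adjusted p = 0.409 with an estimated correlation), where the mitochondrial share was 3.16 ± 0.619% against 5.29 ± 0.259% in Con (SD, n = 3).

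Position markers stood apart here too. Hox genes had 1 higher and 9 lower of 30 (camera adjusted p = 0.000222, adjusted p = 0.272 with an estimated correlation), with Hoxb3 at -2.45 ± 0.32. The distal colon list rose for 2 of 6 (camera adjusted p = 0.0239, adjusted p = 0.409 with an estimated correlation), Atp12a (8.69 ± 1.02) and Hoxb13. The proximal list had 1 higher and 2 lower of 5 (camera adjusted p = 0.00332, adjusted p = 0.127 with an estimated correlation), and the small intestine list 2 lower of 9 (camera adjusted p = 0.0121, adjusted p = 0.28 with an estimated correlation), Sis and Fabp6. Casp14 had no count in any Con library and was at least 303-fold higher in IR+CF-2, against a floor of 3 counts over the group. Casp14, Hoxb13 and the mast cell protease Cma1 owed their means to IR+CF-2 2, with 23.5, 282 and 90.4 CPM there and 0.238, 8.49 and 1.59 in IR+CF-2 1. Hoxa10 had 36.6 ± 27.8 CPM in Con and 65.9 ± 21.1 in IR+CF-2 (0.85 ± 0.70, adjusted p = 0.42). Ctnnb1 was at -0.15 ± 0.14 (adjusted p = 0.465) and Cnr2 at -0.25 ± 0.37 (adjusted p = 0.669).

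At an unadjusted p under 0.05 there were 6824 genes in IR+CF-2 against Con. Without IR+CF-2 2 the counts were 3585 higher and 3136 lower, without Con 2, 3 or 4 they were 489 and 561, 625 and 426, and 358 and 327, and without IR+CF-2 1 or 3 they were 518 and 405, and 814 and 588. The position term left 0 higher and 6 lower, and no list held with an estimated correlation. Fry asks only whether a list moves on balance in a single direction. By fry the lists called by camera passed, except distal colon (adjusted p = 0.0879), fibroblasts (0.0845), interferon-stimulated genes (0.0866) and lipid and ketone metabolism (0.0866).

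Genes past the test in IR against Con and, the other way, in IR+CF-2 against IR numbered 8, all higher in IR than in Con and lower in IR+CF-2 than in IR. They were the phosphatase Ptprd (0.51 and then -0.997), Grin3a (1.49 and -5.11), Fam3c (1.02 and -1.32), Prss23 (1.29 and -2.31), Aplp1 (0.87 and -1.01), Cdkn1c (1.56 and -2.44), Sesn3 (0.51 and -0.89) and Rsad1 (0.69 and -0.97). Ptprd, Fam3c, Aplp1, Sesn3 and Rsad1 fall outside the rule for named genes and were chosen after their values were seen. 1 gene moved the same way in both comparisons, and 1.21 opposite genes were to be expected if the calls were independent. Simulated libraries without effects gave 0, but they held no irradiation effect either, with 0.05 calls on average in IR against Con. That 0 was thus fixed in advance and is not what to expect if irradiation acts and CF-2 does not. Both comparisons use the IR libraries with opposite signs, so their fold changes lean apart by construction. For the difference between IR+CF-2 and IR, CF-2 and the stretch of colon sampled cannot be told apart. Over all genes the covariance of the log2 fold changes was -0.125, against -0.0956 in simulated libraries without effects, a difference of -0.0295. With different IR libraries in each comparison it averaged -0.00739, from -0.182 to 0.198. Signs were opposite in 51% of all genes, against 66.9% in the simulated libraries, which held no irradiation effect, so the shares are not like for like. The count of opposite genes was 128 with DESeq2 and 0 with the position term. It was 63 without IR+CF-2 2, 3 without Con 3 or IR+CF-2 3, 2 without IR+CF-2 1, and 0 without Con 2, Con 4, IR 2 or IR 3.

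**Figure D4:**
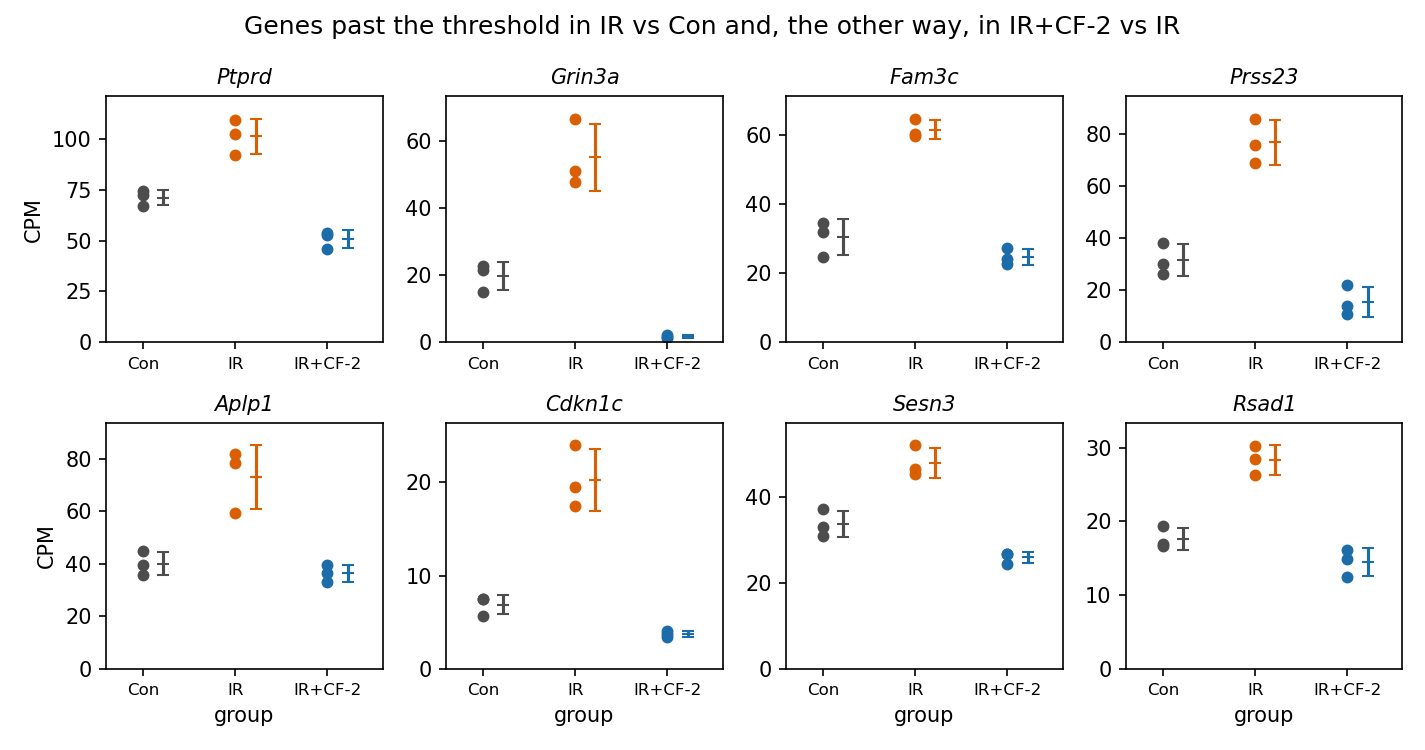
CPM of the 8 genes that were higher in IR than in Con and lower in IR+CF-2 than in IR, by group, with each library (points), group mean and SD (bars, n = 3) and an axis from 0 for each gene. Grin3a has 19.7 ± 4.23 CPM in Con, 55.2 ± 10.1 in IR and 1.6 ± 0.41 in IR+CF-2.

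Of the 616 genes called in IR against Con, 517 (83.9%) were called in the same direction in IR+CF-2 against Con, 392 higher and 125 lower, and 5 in the opposite direction. Independent calls would have shared 51 and 12.9. Simulated libraries without effects shared 0, which was fixed in advance because irradiation changed no gene in them. These comparisons have the Con libraries in common, and the covariance of their log2 fold changes was 0.494, against 0.0945 in the simulated libraries.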

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

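No test in this part was chosen after the result was seen, and the values come from the planned comparisons. In 5 genes the effect against Con went opposite ways with and without CF-2: they were higher in IR than in Con and lower in IR+CF-2 than in Con, and the difference between the treated and untreated irradiated groups passed the test. The comparisons share the Con libraries, and the genes were picked because all 3 comparisons passed the threshold. For the difference between IR+CF-2 and IR, the effect of CF-2 and the stretch of colon sampled cannot be told apart. These genes are among the 8 opposite genes, a count that was 0 without Con 2, Con 4, IR 2 or IR 3. Ptprd and Sesn3 lay close to the threshold in IR against Con (edgeR adjusted p = 0.0464 and 0.0481).

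Cdkn1c, an inhibitor of cyclin-dependent kinases, had 6.86 ± 1.01 CPM in Con, 20.3 ± 3.35 in IR and 3.73 ± 0.289 in IR+CF-2, with a log2 fold change of -2.44 ± 0.19 in IR+CF-2 against IR (edgeR adjusted p = 0.00336). Grin3a, a subunit of NMDA receptors, had 19.7 ± 4.23, 55.2 ± 10.1 and 1.6 ± 0.41 CPM (-5.11 ± 0.27, adjusted p = 0.000311). Prss23, a serine protease, had 31.4 ± 6.07, 76.6 ± 8.6 and 15.4 ± 5.7 CPM (-2.31 ± 0.26, adjusted p = 0.0172). Ptprd, a receptor phosphatase, had 71.2 ± 3.83, 101 ± 8.68 and 50.8 ± 4.4 CPM (-0.997 ± 0.11, adjusted p = 0.0172). Sesn3, a sestrin, had 33.6 ± 3.13, 47.9 ± 3.53 and 25.9 ± 1.33 CPM (-0.89 ± 0.11, adjusted p = 0.0299).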

How the results depend on the processing

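Chosen after seeing the data were 3 alternatives: the position term, robust = FALSE and the fit without Con 3, IR 4 and IR+CF-2 2. Counts are given as higher and lower for IR against Con (454 and 162 as reported), IR+CF-2 against IR (11 and 47) and IR+CF-2 against Con (2152 and 1525), then as opposite genes (8). No named gene changed its direction past the test, and over all alternatives their values kept direction and side of the threshold in 5941 cases, lost the call in 965, gained one in 289 and otherwise moved in 46. The causes were not tested except where stated.

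RLE scaling gave 173 and 104 in the first comparison and 4 opposite genes. Upper quartile scaling gave 166 higher in the first and 4 opposite. Without a filter the first had 215 higher and the second 31 and 90. DESeq2 gave 1330 and 800 in the first, 453 and 491 in the second and 128 opposite. Limma-voom gave 111 and 65 in the first. Fits on the compared groups alone gave 1580 and 727, 2 and 4, 1322 higher in the third, and 2 opposite. With the replicate block the first had 275 lower, the second 1 and 5, the third 213 and 249, and 3 were opposite. No label says that equal numbers belong together. Deviations of equally numbered libraries correlated across genes at 0.259, 0.108 and 0.0891 (Con and IR), 0.202 and 0.0402 (Con and IR+CF-2) and 0.124 and 0.0397 (IR and IR+CF-2), all above 0 but not all over 0.1. Con 3 correlated better with IR+CF-2 1 (0.131) than with its own number there. By construction a threshold of 0.01 gave fewer, 0 and 1, 0 and 5, 190 and 152 and 0, and a 2-fold limit 265 higher in the first, 1102 and 848 in the third and 4 opposite. The stricter filter, robust = FALSE and leaving out abundant and mitochondrial genes moved no count by over 1.5 times.

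The position term gave 15 and 31, 0 and 0, 0 and 6 and 0 opposite. Hoxa13 nearly follows IR and IR+CF-2, so in the second comparison the term takes up their difference by construction. Lost calls there do not show position as the cause. In the third, Hoxa13 was also higher in every IR+CF-2 library (56.8 to 74.9 CPM) than in Con (1.05 to 43.2). That reason does not cover the first, where Con 3 (1.05 CPM) lay among the IR libraries (0.834 to 2.73). Why calls were lost in the first was not tested. Without the 3 libraries that stood apart, a choice that lowers the spread by construction, the counts were 2915 and 1896, 229 and 654, 3913 and 3708 and 181. Leaving out 1 library at a time gave 0 to 789 higher and 1 to 402 lower in the first (highest without IR 4), 0 to 144 and 5 to 453 in the second, 358 to 3585 and 327 to 3136 in the third (highest without IR+CF-2 2), and 0 to 63 opposite.

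Lists called higher and lower were 8 and 8, 14 and 8, and 13 and 11. With an estimated correlation they were 0 and 1, 0 and 0, and 0 and 0. Fry gave 5 and 3 in the first and 0 and 0 in the second. The position term gave 8 higher in the second, and the fit without the 3 libraries 9 and 12, 13 and 10, and 12 and 15. List medians that turned in the second comparison with the position term were those of extracellular matrix (-0.0637), T and NK cells (0.46), fibroblasts (-0.20), smooth muscle (-0.73), endothelial cells (-0.18) and enteric neurons and glia (-0.56). Without the 3 libraries endothelial cells turned to -0.0522 and enteric neurons and glia to -0.26, and the latter ran from -0.0185 (without IR+CF-2 2) to 0.899 (without IR 2) with 1 library left out. In the third, small intestine stood at 0.00987 with the replicate block. Of 17 alternatives, calls were lost without a turn in 7 for Hox and MHC class II genes, 3 for interferon genes, T and NK cells and small intestine and 2 for Wnt ligands in the second, in 6 for lipid and ketone metabolism, 3 for distal colon and 2 for fibroblasts in the third, and in 2 for neutrophils and for Hox genes in the first. With turns that did not pass, they were also lost in 3 for endothelial cells and for enteric neurons and glia in the second and in 2 for small intestine in the third. Calls were gained in 7 for inflammatory cytokines, 6 for endothelial cells and 3 for MHC class II genes in the first, 4 for lipid and ketone metabolism in the second, and 5 for Wnt ligands and 3 for smooth muscle and for enteric neurons and glia in the third. No other described list lost a call in more than 1 or gained one in more than 2.

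With 3 mice per group about 3 in 4 of the 4-fold changes and under 1 in 4 of the 2-fold changes were recovered in simulation, and folds against a group with few counts depend on the fit.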

Other observations

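All tests of explanations in this part, and the regroupings of libraries, were chosen after the results were seen; the list tests were planned. The tests of position, of muscle and of Con 3 were also redefined after a first run had shown their values. Among the 10 lists not described so far, enteroendocrine cells had a median of 0.26 (camera adjusted p = 0.294) in IR against Con. In IR+CF-2 against IR its median was -0.59 (camera adjusted p = 0.163) and its mean 0.03, and Insl5 rose alone, with 40, 171 and 25.2 CPM in the treated mice. Goblet cells had medians of 0.34 (camera adjusted p = 0.325), -0.14 (camera adjusted p = 0.185) and 0.27 (camera adjusted p = 0.992) in the 3 comparisons, with a mean of 0.15 in the second. Apoptosis regulators had 0.09 (camera adjusted p = 0.208), -0.07 (camera adjusted p = 0.35) and 0.00 (camera adjusted p = 0.614), and 2 of 20 rose with irradiation. Antimicrobial genes of the epithelium had 0.25 (camera adjusted p = 0.896), -0.46 (camera adjusted p = 0.188) and -0.22 (camera adjusted p = 0.495).

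Circadian clock genes had medians of 0.04 (camera adjusted p = 0.548), -0.15 (camera adjusted p = 0.199) and -0.23 (camera adjusted p = 0.192), and glucocorticoid response genes -0.09 (camera adjusted p = 0.601), -0.07 (camera adjusted p = 0.189) and -0.07 (camera adjusted p = 0.206). Mast cells had -0.62 (camera adjusted p = 0.44), 1.12 (camera adjusted p = 0.18) and 0.51 (camera adjusted p = 0.992), erythrocytes -0.88 (camera adjusted p = 0.164), 0.53 (camera adjusted p = 0.381) and -0.33 (camera adjusted p = 0.55), and adipocytes -0.64 (camera adjusted p = 0.0857), 1.54 (camera adjusted p = 0.148) and 0.56 (camera adjusted p = 0.693). The mean of the clock list in the first comparison was -0.09, opposite to its median. In the third comparison camera gave the direction of the goblet, enteroendocrine and adipocyte lists as down, where their medians were 0.27, 0.02 and 0.56. Pancreatic acinar cells had 1 measured gene and were not tested.

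HoxA genes 9 to 13 were mostly high in IR+CF-2, Con 2 and Con 4 and low in IR and Con 3. Exceptions were Hoxa13 in Con 4 (8.07 CPM) and Hoxa11 in IR+CF-2 2 (6.11 CPM, near 5.46 in IR 2). More muscle in the samples is argued against as the whole cause, since the 4 HoxA genes differed between IR+CF-2 and IR by 2.99 ± 0.461 (log2, standard error between libraries) beyond the smooth muscle list. A different stretch of colon may have been sampled: without HoxA genes the distal list had a median of 3.58 and the proximal list -2.50, a difference of 6.08. The lists still hold Hoxb13 (distal) and Hoxb6 and Hoxb8 (proximal), so they partly restate the HoxB difference. With an estimated correlation the adjusted p over these 2 lists was 0.0886 and 0.0216 (camera), and 0.256 for the proximal list over all lists. Con 2 and Con 4 had high Hoxa9 and Hoxa10 without the low HoxB level of IR+CF-2. Hoxa13, however, had 8.07 CPM in Con 4 against 56.8 to 74.9 in IR+CF-2. That CF-2 raised HoxA genes in irradiated colon stays open too, since Hoxa10 varied 10.3-fold among untreated Con mice, at or above 99.8% of the 11673 genes with a Con mean of at least 5 CPM. Position and CF-2 cannot be told apart here, because no group received CF-2 without irradiation and no label gives the stretch of colon.

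In the main fit IR+CF-2 differed from Con in more genes than IR did. With the replicate block the order turned, with 669 higher and 275 lower for IR and 213 and 249 for IR+CF-2, though no label says that equal numbers belong together. The nearness of IR 4 to Con is a candidate explanation: the variance of effects across genes was 0.378 for IR, 0.502 without IR 4 and 0.596 for IR+CF-2, with ranges over pairs of libraries that overlap (0.428 to 0.585 without IR 4 and 0.341 to 0.872 for IR+CF-2). Without IR+CF-2 2 it was 0.835 (0.799 to 0.872), above the range of IR without IR 4. That CF-2 changed further genes on top of irradiation may also hold, since 58 genes passed the test in IR+CF-2 against IR, and the loss of these calls with the position term, which nearly follows the groups, decides nothing. The libraries are too few to decide between them, and the stretch of colon sampled cannot be told apart from CF-2 here. In IR+CF-2 against Con the distal and proximal colon lists had medians of 3.24 and -2.64, though neither list held with an estimated correlation.

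Interferon-stimulated genes were lower in IR than in Con. The high level of Con 3 is argued against as the whole cause, since without it the list mean was still lower in IR, with a difference of -1.22 ± 0.379 (log2, standard error between libraries). Loss of T and NK cells could lower them as well, and no other biological explanation was tested. In IR+CF-2 against IR the interferon median was 0.72 and the T and NK median -0.50, but neither list held with an estimated correlation. With the position term both were above 0 (1.71 and 0.46), and without IR+CF-2 1 the interferon median was 0.27, so this stays open.

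Other splits of the 6 libraries of a comparison number 10 with the real split, too few for a share under 0.05. For genes the real splits gave 616, 58 and 3677 calls and the highest other split 0 in each, so 1 of 10 splits gave as many. Every other split mixes libraries of both groups, so a real difference would add to the spread within them. Their 0 thus does not decide whether chance gave these counts. For lists the real splits gave 16, 22 and 24 calls and the highest others 19, 22 and 21, with 4, 2 and 1 of 10 splits giving as many. Of 100 regroupings of the 9 libraries, the real one included, 2 gave at least 8 opposite genes, but most mix Con with irradiated libraries and gave 0, so they do not decide whether chance gave the 8. The highest other, 451, had the 3 Con libraries in the place of IR, where genes that irradiation moves alike in both other groups count as opposite by construction. With Con kept and the 6 irradiated libraries relabelled, 18 of 20 relabellings gave 0 and the swap of IR with IR+CF-2 gave 54, and 20 are too few for a share under 0.05.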
